A study of Rattus norvegicus with 16 samples.

How the data were processed

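Adult male Wistar rats of 240 to 260 g received a single injection of streptozotocin, 55 or 100 mg/kg, into a tail vein, per the labels' protocols; blood glucose above 13 mmol/L was checked after 24 hours. Hearts were drained of blood after 4 days of follow-up. RNA was isolated with TRIzol, and libraries were made from 400 ng of total RNA with a stranded kit that selects polyadenylated RNA, then sequenced on an Illumina NextSeq instrument, per the labels. Each library came from its own rat (control n = 4, D55 n = 6, D100 n = 6), per the labels. They name no batch, litter or sequencing run, so no such term could be fitted.

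The deposited values are estimated counts per gene for each library, made with kallisto 0.43.1 on the rat build Rnor_6.0, per the submitters' processing notes. Kallisto assigns each read to the transcripts it is compatible with and divides reads shared by several of them, so an estimated count need not be whole. An estimate was called whole when it lay within 0.01 of a whole number, judged only for estimates that round to at least 1 and lie under 10000, since many larger ones are written without decimals. By this measure 16.1% to 25.9% of the estimates in a library were not whole. A gene with estimates that are rarely whole shares its reads with similar sequences and is measured less surely. The annotation release, the strand setting and any read filter are not given in the sources used here.

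Estimated counts were rounded to whole numbers. Each of the 23918 genes is named by a versioned Ensembl identifier, and the files do not pair these with symbols. The reference gene table used here (RefSeq on the GRCr8 assembly, 47357 rows) holds 0 rows with an Ensembl identifier, so 0 identifiers matched and names were not inferred. The 42 gene lists and the genes fixed by symbol before the data were examined could for that reason not be tested, nor could coordinates, gene length or GC content be used. The rule fixed beforehand for naming genes took those with the largest rise or fall among genes past the threshold, with a mean of at least 5 CPM and no overlap between the groups. It also required a symbol, a condition that could not be applied, and it was used here for D100 against control alone, limited to 2 identifiers in each direction out of 391 genes that qualified.

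Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr with the 3 groups, which left 14175. TMM scaling factors were used, and a quasi-likelihood model (glmQLFit, glmQLFTest) with 1 coefficient per group was fitted over all 16 libraries, which share an estimate of the spread. P-values were adjusted by Benjamini-Hochberg within each comparison with a threshold of 0.05. CPM values use TMM-scaled library totals. Principal components were computed on log2 CPM with a prior count of 2. Single values per library were compared by exact two-sided permutation tests, adjusted over the 3 comparisons of a measure. For a gene at 0 in all 4 controls a lower bound of the fold was computed against 3 counts over the pooled controls.

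Total counts ranged from 4.685 to 48.4 M per library, so 3 counts correspond to between 0.0412 and 0.619 CPM. Pairs of libraries within a group were compared by a chi-square test on genes with at least 10 counts in the pair; the lowest chi-square per degree of freedom was 12.1, so none was a duplicate of another.

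The test was tried on simulated counts with the means and totals of the real libraries and 200 genes changed by known folds. For D100 against control it recovered 2.99% of 1.5-fold, 32.8% of 2-fold and 89.4% of 4-fold changes, with 3 false calls among 13982 tested genes. For D100 against D55 it recovered 22.7% of 2-fold changes, with 1 false call, and for D55 against control 9.09%, with 0 false calls. Each changed gene had a D55 fold that was the square root of its D100 fold. Genes were drawn independently, so the false calls leave out variation that many genes share.

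Alternatives fixed before the data were examined were the scaling of DESeq2 1.42.0 and no scaling, leaving out the 10 most abundant genes, no filter and a stricter one (5 CPM in 4 libraries), the tests of DESeq2 and of limma-voom with quality weights (limma 3.58.1), a robust spread, fits of the compared groups alone, 1 surrogate variable (sva 3.50.0), a 1.5-fold threshold, leaving out each library, and the replicate letter as a block. Chosen after seeing the data were leaving out D55 B and E, alone or with D100 F, the share of the 10 most abundant genes as a covariate, and thinning the counts to one depth. The effect of the controls shared by both doses was estimated from 20 simulations of unchanged groups and from 6 assignments of split controls, and both were repeated, as chosen after seeing the data, without D55 B and E and with the covariate. Label splits were drawn 100 at a time, the real split included.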

Results

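Heart RNA was sequenced from 16 adult male Wistar rats in 3 groups: 4 untreated controls, 6 rats given streptozotocin at 55 mg/kg (D55) and 6 given 100 mg/kg (D100). Streptozotocin is toxic to the insulin-producing beta cells of the pancreas and is used to make rodents diabetic. The title of the study asks how the severity of diabetes is mirrored in cardiac gene expression, so the groups were compared as D55 against control, D100 against control and D100 against D55. Hearts were taken after 4 days of follow-up, and each library came from a separate animal.

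The total estimated count per library averaged 34.5 M ± 9.56 (SD, n = 4) in the controls, with a range of 26.21 to 48.27 M. D55 libraries held 34.4 M ± 11.3 (SD, n = 6; 18.5 to 48.4) and D100 libraries 20.2 M ± 7.87 (SD, n = 6; 4.685 to 25.58). D100 libraries were shallower than control libraries by an exact two-sided permutation test (p = 0.00476, 0.0143 adjusted over the 3 comparisons). Against D55 the same exact test gave p = 0.039, or 0.0585 after adjustment. The shallowest library, D100 replicate F, held 4.685 M counts and had counts for 13290 genes, against 15253 to 16397 genes in the other D100 libraries.

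The 10 most abundant genes of the whole series took 49.7% ± 7.60 (SD, n = 4) of the counts in controls, 43.6% ± 11.1 (SD, n = 6) in D55 and 60.8% ± 5.90 (SD, n = 6) in D100. This share was 17.2 percentage points higher in D100 than in D55 (exact two-sided permutation p = 0.00649, adjusted 0.0195). It was 11.1 points higher in D100 than in control, with an exact p of 0.0381 that rose to 0.0572 after adjustment. The difference of D55 from control, -6.11 points, was smaller than the spread between replicates (exact p = 0.371). D55 replicates B and E had the lowest shares of the series, 30.1% and 30.4%. Without these libraries the D55 mean was 50.2% ± 5.21 (SD, n = 4), and D100 was 10.6 points higher than D55 (exact p = 0.019).

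The first principal component of log expression held 51.9% of the variance and followed the share of the 10 most abundant genes. Over all 16 libraries Pearson's r was 0.982 and Spearman's rho 0.944, each with a permutation p of 1e-05, the smallest that 100000 permutations can give, and an adjusted p of 3e-05 over 3 relations. With D55 B and E left out, r was 0.961. The relation was also present within each dose group: r was 0.992 over the 6 D55 libraries and 0.970 over the 6 D100 libraries, each with an exact permutation p of 0.00556. Spearman's rho was 0.886 in either group, with an exact p of 0.0333. Without the 2 libraries farthest from the group median, r over the remaining 4 was 0.947 in D55 and 0.884 in D100. No correlation was computed for the 4 controls, in which shares of 43.3, 44.0, 51.9 and 59.4% went with component 1 scores of -40.8, -31.0, -6.27 and 41.7. Component 1 scores averaged -9.09 ± 36.8 (SD, n = 4) in controls and -46.0 ± 68.7 (SD, n = 6) in D55. In D100 they averaged 52.1 ± 49.7 (SD, n = 6). No group difference on component 1 passed 0.05 after adjustment over the 3 comparisons. D100 against D55 gave an exact permutation p of 0.0216 (adjusted 0.0648). D100 against control gave an exact permutation p of 0.0714 (adjusted 0.107), and D55 against control an exact permutation p of 0.367. On the third component, with 5.61% of the variance, D100 libraries scored 13.4 ± 11.9 (SD, n = 6) and controls -25.9 ± 4.88 (SD, n = 4; exact p = 0.00476, adjusted 0.0143). D55 libraries scored 3.82 ± 24.0 (SD, n = 6), with an exact p of 0.0333 against control (adjusted 0.05) and 0.413 against D100.

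**Figure D1:**
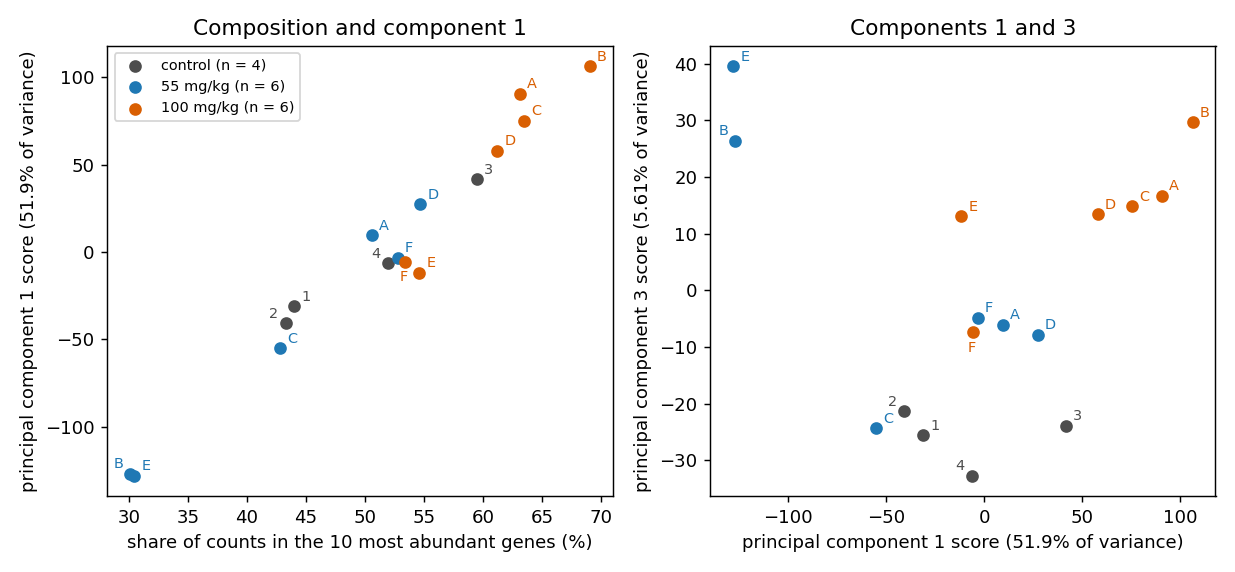
Each point is 1 library, coloured by group and marked with its replicate. Left, the share of counts in the 10 most abundant genes (%) against the score on principal component 1; the points lie near one line (r = 0.982), with D55 B and E at its low end. Right, scores on components 1 and 3; the 4 controls lie between -32.7 and -21.3 on component 3.

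Genes carry Ensembl identifiers alone in the files, and the files do not pair them with gene names; of the 23918 identifiers, 0 matched the reference gene table used here. Individual genes are therefore given by identifier, 2 that rose and 2 that fell, and no statement on pathways or cell types was made.

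The comparison of D100 with control asked which cardiac transcripts differed after the higher dose. Of 14175 genes tested, 621 (4.38%) differed at an adjusted p of 0.05: 272 were higher and 349 lower in D100. The median fold change was 2.03 among the higher genes and 2.10 among the lower, and 327 genes changed at least 2-fold, 141 upward and 186 downward. The share of genes called grew with abundance, from 2.26% of the 1905 genes under 1 CPM to 19.5% of the 41 genes over 1000 CPM; 4 of those 41 rose and 4 fell. The 10 most abundant genes all had higher fitted levels in D100 (9 of 10 without scaling factors), with a median log2 fold change of 0.75 (0.29 without scaling factors). In edgeR 0 of them passed and 6 had an unadjusted p under 0.05, while DESeq2 called 2 and limma-voom 10. Of all 14175 tested genes, 3227 had an unadjusted p under 0.05 in edgeR, while DESeq2 called 1438 and limma-voom 9595. Values of the D100 and control libraries did not overlap for 533 of the 621 genes (85.8%), against 7.57% of all tested genes and 0.952% by chance.

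Among the genes that rose, ENSRNOG00000034228.5 stood at 1.69 CPM ± 0.34 (SD, n = 4) in controls, 10.3 ± 4.92 (SD, n = 6) in D55 and 41.2 ± 9.38 (SD, n = 6) in D100. Its log2 fold change in D100 over control was 4.61 (SE 0.42, edgeR adjusted p = 4.27e-05). ENSRNOG00000030351.4 had a rounded count of 0 in all 4 controls and 34.9 CPM ± 22.3 (SD, n = 6) in D100, with counts of 60 to 991. Its level was at least 1760-fold higher than in controls, computed against 3 counts over the pooled controls, a floor of 0.0198 CPM that covers counting error only (edgeR adjusted p = 0.0462). In D55, 3 of 6 libraries were also at 0, and the others held 1.92, 29.0 and 44.6 CPM. In the 9 libraries with a count of this gene, 0 estimates were within 0.01 of a whole number, so part of its reads were shared with other sequences and its level is uncertain. The call held in 16 of 32 alternative settings.

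ENSRNOG00000025757.2 fell from 3626 CPM ± 1465 (SD, n = 4) in controls to 302 ± 225 (SD, n = 6) in D100, a log2 fold change of -3.59 (SE 0.53, edgeR adjusted p = 0.00127). ENSRNOG00000022932.4 fell from 14.2 CPM ± 11.4 (SD, n = 4) to 1.5 ± 0.64 (SD, n = 6), a log2 fold change of -3.21 (SE 0.55, adjusted p = 0.00375). Its estimates were within 0.01 of a whole number in 0 of 16 libraries, and those of ENSRNOG00000025757.2 in 1 of the 6 libraries where they lay under 10000, so reads of either gene were partly shared with other sequences. The rule for naming genes required no overlap, so for both the highest D100 value lay below the lowest control value. These were 733.8 against 2185 CPM and 2.75 against 3.36 CPM.

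The size of the D100 list depended on the libraries used. It fell to 180, 205 and 213 genes without control 1, 2 or 4, and to 329, 298, 349 and 314 without D100 A, B, C or D; it rose to 1086 without D100 E and to 1493 without D55 B and E, whose spread enters the shared error estimate. All 615 of the called genes still tested without D55 B and E stayed called in the same direction. DESeq2 called 1438 genes and limma-voom 9595, and with 1 surrogate variable the count was 342. Without scaling factors 90 genes were higher and 1084 lower, while the median log2 change of all genes moved from -0.03 to -0.48.

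**Figure D2:**
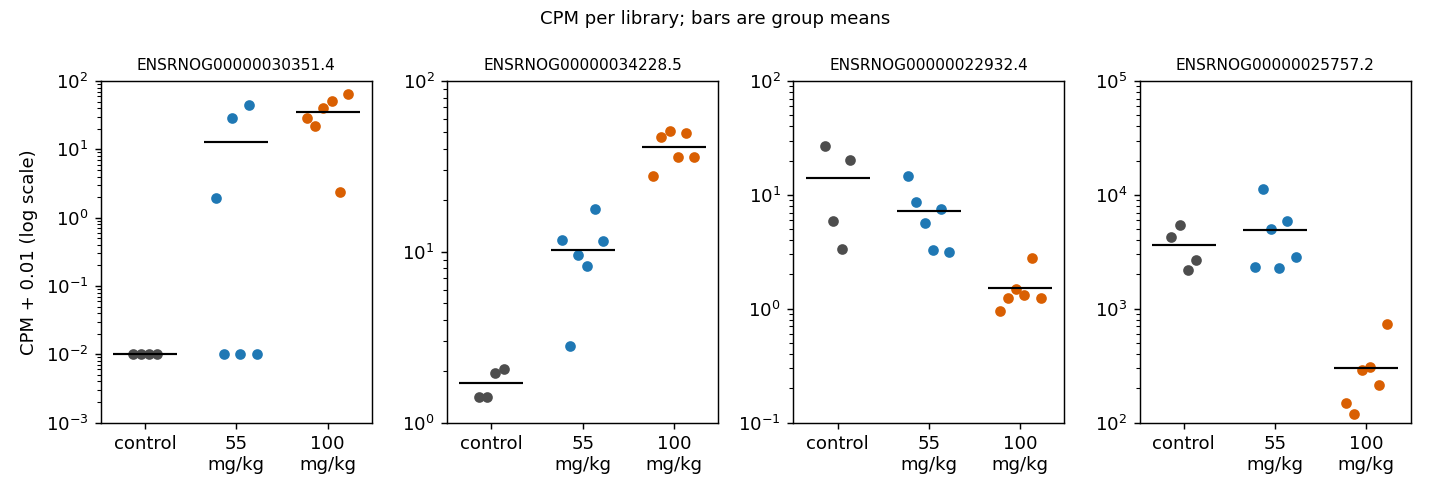
Expression of the 4 identifiers in each library, in CPM plus 0.01 on a log scale that differs between panels; points are libraries (control n = 4, D55 n = 6, D100 n = 6) and bars are group means. ENSRNOG00000034228.5 is lowest in the controls and highest in D100, and D55 libraries of ENSRNOG00000030351.4 are at 0 in 3 of 6.

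The comparison of D55 with control asked the same of the lower dose. Only 9 of 14175 genes passed the threshold, 8 higher and 1 lower in D55, while 1271 had an unadjusted p under 0.05. The 8 higher genes had a median fold change of 2.51 and the lower one was 3.47-fold lower. Values of the D55 and control libraries did not overlap for any of the 9, against 2.55% of all tested genes and 0.952% by chance. ENSRNOG00000034228.5 was among the higher genes, with a log2 fold change of 2.60 (SE 0.38, edgeR adjusted p = 0.0231), a call that held in 25 of 32 alternative settings. ENSRNOG00000030351.4 did not pass in edgeR (log2 fold change 11.6, adjusted p = 0.546). It passed in 1 of 31 settings, DESeq2 (log2 fold change 24.3, adjusted p = 1.91e-20). With a rounded count of 0 in all 4 controls and 3 D55 libraries, the size of this fold is not set by the data. ENSRNOG00000022932.4 did not pass in edgeR either, at 7.15 CPM ± 4.30 (SD, n = 6, log2 fold change -0.99, adjusted p = 0.554). ENSRNOG00000025757.2 had 4924 CPM ± 3396 (SD, n = 6) in D55, a log2 fold change of 0.44 that did not pass (adjusted p = 0.749) and that was -0.21 without D55 B and E.

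The D55 list rested on few libraries: edgeR called 0 genes without any 1 of the 4 controls (593 to 1229 at an unadjusted p under 0.05) and 0 without D55 F (1657 unadjusted). It called 5 without D55 A, 4 without D55 E or without D100 C, 15 without D55 B and 14 without D55 B and E. With all libraries DESeq2 called 88 genes (52 higher, 36 lower) and limma-voom 522 (262 higher, 260 lower). Without scaling factors 5 were higher and 0 lower in edgeR (975 unadjusted), with the median of all genes at 0.20 instead of 0.03. In simulated counts with 200 changed genes among 13982 tested, the D55 comparison recovered 9.09% of 2-fold changes and 0% of 1.41-fold changes, while the D100 comparison with control recovered 32.8% of 2-fold and 89.4% of 4-fold changes. The simulated D55 folds were the square root of the D100 folds, so the comparisons did not have equal signal.

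The direct comparison of the doses, D100 against D55, gave 5041 of 14175 genes (35.6%), 1944 higher and 3097 lower in D100. The median fold change was 1.69 among the higher and 2.50 among the lower genes, and 2533 genes changed at least 2-fold, 372 upward and 2161 downward. Higher genes were more often abundant: of the 41 genes over 1000 CPM, 18 rose and 6 fell, while of 5724 genes at 1 to 10 CPM, 426 rose and 1610 fell. Of the 10 most abundant genes, 8 rose (5 without scaling factors), with a median log2 fold change of 1.09 over all 10 (0.48 without scaling factors). Only 571 of the 5041 genes (11.3%) had no overlap between the dose groups, against 4.2% of all tested genes and 0.216% by chance. For 4305 of the 5041 (85.4%) the control mean lay between the means of the doses.

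ENSRNOG00000034228.5 was higher in D100 than in D55 by a log2 fold change of 2.01 (SE 0.31, edgeR adjusted p = 0.00546). ENSRNOG00000025757.2 was lower, at -4.03 (SE 0.52, adjusted p = 0.00208), and so was ENSRNOG00000022932.4, at -2.22 (SE 0.51, adjusted p = 0.0153). The call of ENSRNOG00000022932.4 was lost without D55 B and E (log2 fold change -2.12, adjusted p = 0.0885) and without D100 F too (adjusted p = 0.0734). It was also lost with the share of the 10 most abundant genes as a covariate (-1.73, adjusted p = 0.321), in limma-voom (adjusted p = 0.0709) and with the 1.5-fold threshold (adjusted p = 0.0768). Over its 32 settings the adjusted p was 0.000298 to 0.321. The call of ENSRNOG00000034228.5 was lost with the covariate (1.93, adjusted p = 0.0612) and with the 1.5-fold threshold (adjusted p = 0.0582), and its adjusted p was 1.13e-07 to 0.0612 over 32 settings. ENSRNOG00000030351.4 did not differ past the threshold in edgeR (adjusted p = 0.386). It passed in 1 of 32 settings, limma-voom (log2 fold change 8.21, adjusted p = 0.00152).

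Most calls between the doses were lost without D55 replicates B and E, the libraries with the lowest share of counts in the 10 most abundant genes. Then 123 genes differed, 64 higher and 59 lower, of which 120 were among the 4966 earlier calls still tested. Over those 4966 genes the median log2 change in the direction first called went from 0.99 to 0.60, with the same sign in 100%. With the share of the 10 most abundant genes as a covariate 40 genes differed. Without scaling factors 141 were higher and 6870 lower, with the median log2 change of all genes at -0.65 instead of -0.03. Leaving out 1 library gave 1172 genes without D55 B and 1403 without D55 E, and 1965, 1721, 2173 and 2722 without D100 A, B, C or D. Fitting these groups alone gave 3016, and 0 with the replicate letter added as a block, though libraries of the same letter showed no clear pairing. A 1.5-fold threshold, which asks for more, gave 5.

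**Figure D3:**
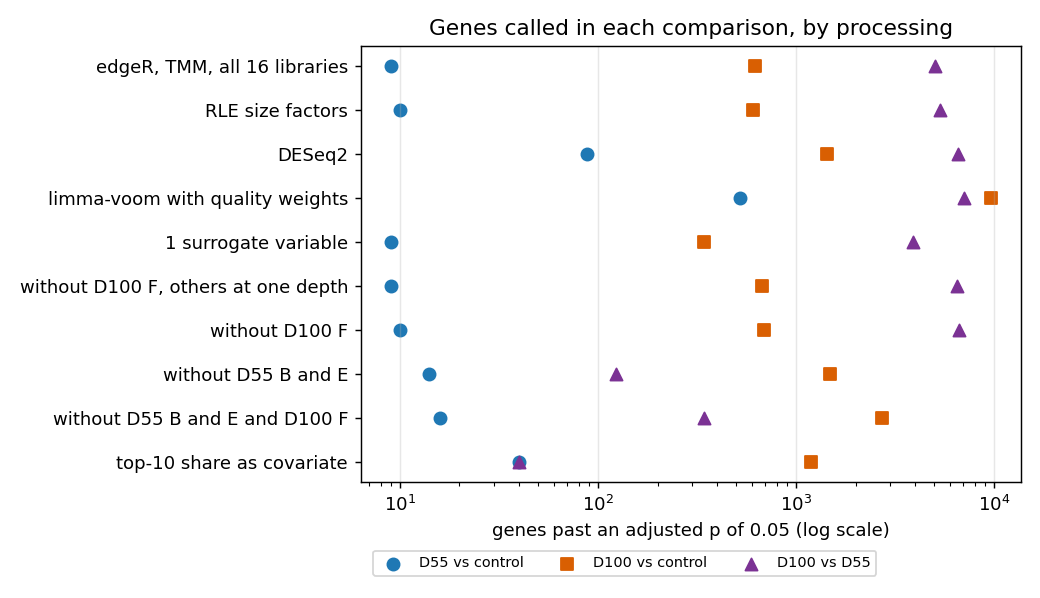
Genes past an adjusted p of 0.05 in each of the 3 comparisons (log scale) under 10 settings, 1 per line. Counts for D100 against D55 run from 40 with the covariate to 7068 with limma-voom, and stand at 123 without D55 B and E.

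The doses were also compared through their changes from control. Of the 621 genes called in D100 against control, 524 (84.4%) had a D55 fold change of the same sign, smaller than the D100 change in 513 and larger in 11. The median size of the D100 change was 1.04 on the log2 scale, and the median D55 change in that direction was 0.25. Between the doses, 481 of the 621 also differed in the same direction and 0 in the opposite direction by edgeR (1 at an unadjusted p under 0.05). Without D55 B and E this was 116 of 1493 genes, and with the share of the 10 most abundant genes as a covariate 38 of 1194. These comparisons share the D100 libraries: in 20 simulations of unchanged groups, 126 (107 to 152) of the 621 genes with the smallest p in D100 against control also had an unadjusted p under 0.05 between the doses, against 528 observed. Of all 14175 tested genes, however, 7286 had an unadjusted p under 0.05 between the doses by edgeR and 35.6% were called. The simulations lack this background, so the excess over them does not by itself show a change graded by dose. Of the 9 genes called in D55, 8 were called in D100 with the same direction, 6 of the 9 had a larger D100 change, and 4 were called in all 3 comparisons. Independent lists of these sizes would share 0.154 higher and 0.0246 lower genes, but these lists share their controls. Splitting the controls could not test this overlap, since D55 then had 0 calls.

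Both doses were set against the same 4 controls, which by itself makes their changes tend to share a sign. In 20 simulations of unchanged groups, each gene had 1 spread for all groups, which D55 B and E raise (common dispersion 0.152, or 0.0952 without them). Of the 621 genes with the smallest p, 93.8% had the same sign in these simulations (91.3 to 94.7), more than the 84.4% observed, and 0 genes were called in both. Without D55 B and E the order was the opposite: 93.6% of the 1493 D100 calls had the same sign in D55, against 88.4% (87.0 to 89.7) in simulations of that setting. With all libraries, the ratio of the median D55 to the median D100 change was 0.242, against 0.564 (0.539 to 0.592) in the simulations. Without D55 B and E these medians were 0.264 and 0.892 on the log2 scale, and no ratio was simulated for that setting. When the controls were split so that each dose had its own 2, the share of D100 calls with the same sign in D55 was 72.4% to 96.8% over 6 assignments, with 56 to 214 D100 calls and 0 D55 calls by edgeR (285 to 1296 unadjusted); without D55 B and E it was 53.6% to 99.3%. Across all 14175 genes, which are not independent replicates, the D55 and D100 changes had a correlation of -0.01 and a covariance of -0.00604, against 0.607 and 0.115 in the simulations. With split controls the correlation averaged -0.06 (-0.36 to 0.27). Without D55 B and E the correlation was 0.53, against 0.54 (0.50 to 0.55) in the simulations, and the covariance 0.141, against 0.0804 (0.0682 to 0.0884). With the controls split this correlation averaged 0.28 (-0.06 to 0.51) and the covariance 0.0898 (-0.0273 to 0.152).

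**Figure D4:**
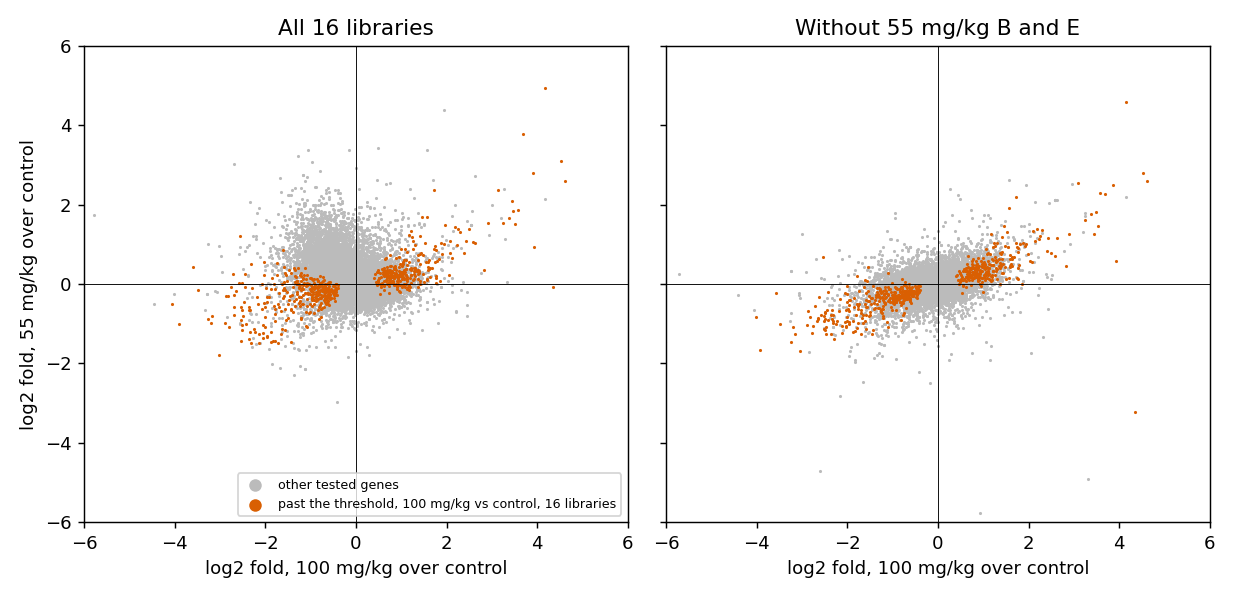
Log2 fold changes of D100 (horizontal) and D55 (vertical) over control for 13854 genes tested with all 16 libraries and without D55 B and E; 9 genes lie beyond the axes at 6. Orange points passed the threshold in D100 against control with all libraries. The correlation across all tested genes is -0.01 with 16 libraries (left) and 0.53 without B and E (right), where simulated unchanged groups gave 0.61 and 0.54.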

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

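The tests of D55 B and E and of the share of same-sign genes with split controls were chosen after their results had been seen. The covariate and the thinning were added after the data had been seen but before their own results, and the other tests reported here were chosen before. In 5 of 33 groups of values, 1 library lay far from the rest of its group, where chance would give about 1.65.

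Of the 5, 4 concern D100 replicate F, 1 of them the level of ENSRNOG00000025757.2. Its total was 4.685 M counts (others 20.32 to 25.58 M), it had counts for 13290 genes (others 15253 to 16397), and it scored 152.8 on the second principal component (others -7.23 to -2.03), which held 18.96% of the variance. Low depth alone was tested by thinning the other 15 libraries to its total: its gap to the nearest library on the component that sets it apart, divided by the range, went from 0.905 to 0.764, where depth as the cause predicted a fall by at least 50%, so the tables argue against depth as the whole cause. After thinning it still had fewer genes with a count (13290) than any other library (13561 to 15641). What else sets this library apart stays open, and no biological explanation was tested, since its dose is that of the other D100 rats.

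ENSRNOG00000025757.2 stood at 733.8 CPM in D100 F, against 118.1 to 308.5 CPM in the other D100 libraries. ENSRNOG00000022932.4 stood at 2.75 CPM in D100 E, against 0.951 to 1.49 CPM in the others.

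The calls between the doses, 5041, far outnumber the 621 and 9 calls of either dose against control, and the tables argue against lower depth in D100 as the cause: without D100 F the count was 6682, and with the remaining libraries thinned to one depth it was 6512. Without D55 B and E the count was 123, but these libraries were picked because they stood apart and the count was known, so it describes the pattern and is no test of its cause. Within the 4 untreated controls, 95.9% of the called genes had a slope on the share of the 10 most abundant genes of the same sign as their change. So did 84.8% of all tested genes, which also passes the mark set beforehand. With that share over all genes, a list of called genes could hardly miss the mark. The test therefore does not set the called genes apart from the rest and is weak support. A candidate explanation is an axis of library composition that is present without streptozotocin. With this share as a covariate the median change of the called genes went from 1.0 to 0.13 on the log2 scale (median SE 0.30 to 0.21), so the calls ended because the change shrank. An effect of the dose on that axis stays open as a biological explanation, since D100 kept a higher share than the remaining D55 libraries and the covariate follows the groups.

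Of the genes called in D100 against control, most had a smaller D55 change of the same sign, which the shared controls could produce. With split controls the share of the same sign was never below 72.41% (53.6% without D55 B and E). Every split reuses the same treated and control libraries, and many genes vary together, so these shares are not independent of each other. A difference common to all controls would also remain after the split. The split therefore cannot tell whether the shared controls are the only source of the shared sign. With no effect the shared controls gave 93.8% in simulations that draw genes independently, more than the 84.4% observed, but without D55 B and E they gave 88.4%, less than the 93.6% observed, so the simulations do not settle it. Across all genes the test fixed beforehand was the mean correlation with split controls, -0.05931; a value of 0 or below was to point to the shared controls, but with all libraries the correlation was already -0.01, so there was no positive correlation to explain and the test decides nothing, a reading made after the value was seen. A response to streptozotocin that grows with dose stays open and was not tested apart from this.

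For D100 against control, 100 of the 210 possible splits of the libraries were drawn. Only 1 of the 100, the real one, called 621 genes or more, and the highest other called 1. That is fewer than the 5 that were to mark chance. A draw of 100 splits cannot show a rarity below 1 in 100, so chance is made unlikely but not excluded. For D100 against D55, 2 of 100 called 5041 or more, fewer than the 5 set beforehand as the mark of chance. The highest other called 7934, with D55 A, B, C and E and D100 E and F on one side. A mixed grouping can thus give a list of this size, so chance is not excluded for it. This points to a structure of the samples. Of the other splits, 43 had D55 B and E on the same side. The median count of these was 0, as it was with B and E on different sides. The highest other count with D55 B and E on different sides was 2. For D55 against control, 5 of 100 called 9 genes or more, so chance cannot be excluded; the highest other called 3293, with controls 1, 2 and 4 and D55 B, C and E together, again a structure of the samples.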

How the results depend on the processing

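The settings that leave out D55 B and E, alone or with D100 F, the covariate, their split controls and the thinning were chosen after seeing the data. Counts are given for D55 and D100 against control and D100 against D55, in that order (main values 9, 621, 5041); where a setting moved a count over 1.5 times and no cause is named, the cause was not tested. Scaling by DESeq2's size factors (10, 604, 5322), leaving out the 10 most abundant genes (8, 616, 4853), the strict filter (11, 626, 4184), a robust spread (9, 606, 4964) and leaving out D100 F with the rest thinned (9, 673, 6512) kept all 3 counts within 1.5 times. No scaling gave 5, 1174 (90 higher, 1084 lower) and 7011 (141 higher, 6870 lower), as the median of all genes moved to 0.20, -0.48 and -0.65 on the log2 scale, from 0.03, -0.03 and -0.03. No filter gave 8, 409 and 4411, with 19789 genes tested. DESeq2 gave 88, 1438 and 6600, with 53.9% of the D100 calls against control higher (43.8% in the main test), and limma-voom 522, 9595 and 7068. With 1 surrogate variable, which mainly marks D100 F (0.849 in it, -0.228 to 0.261 in the others), there were 9, 342 (53.8% higher) and 3885; fitting the compared groups alone gave 1, 841 and 3016. A 1.5-fold threshold in edgeR asks for more and gave 0 (375 at an unadjusted p under 0.05), 70 and 5. Without D55 B and E there were 14, 1493 and 123, and without D100 F too 16, 2731 and 342; the common dispersion went from 0.152 to 0.0952 without B and E. The covariate gave 40, 1194 and 40. Thinning to the shallowest library, where only 11619 genes could be tested, gave 4, 346 and 3361, so a depth that low went with fewer calls.

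Leaving out each library gave 0 to 15, 180 to 1086 and 1172 to 6743. The lowest were without control 1 (also 0 without control 2, 3 or 4 or D55 F, with 593 to 1657 unadjusted), control 1 and D55 B, the highest without D55 B, D100 E and D55 D. Counts also moved over 1.5 times without D55 A (5), E (4) or D100 C (4) in the first; control 2 (205) or 4 (213) or D100 A (329), B (298), C (349) or D (314) in the second; and D55 E (1403) or D100 A (1965), B (1721), C (2173) or D (2722) in the third.

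The correlation of D55 and D100 changes, -0.01, ranged from -0.13 to 0.17 over these fits, the highest without D55 B, and was 0.53 without D55 B and E and 0.46 with the covariate, where simulated unchanged groups gave 0.54 and 0.37, and splitting the controls 0.28 and 0.26 (-0.06 with all libraries). The 8 genes called in both comparisons with control became 14 and 37 in those settings (0 and 0.05 in the simulations), on average 1.17 and 4.67 with the controls also split, and 0 to 14 with 1 library left out (14 without D55 B). The 0 without any 1 control or D55 F, and with the controls split and all libraries used, follows from 0 calls in D55. ENSRNOG00000025757.2 in D55 against control turned from 0.44 to -0.56 with limma-voom (adjusted p = 0.33), -0.21 without D55 B and E, -0.21 without D100 F too, and -0.25 with the covariate; over its 32 settings the adjusted p was 0.33 to 1. ENSRNOG00000034228.5 and both identifiers that fell kept their call in D100 against control in 32 of 32 settings. In D100 against D55, ENSRNOG00000025757.2 kept it in 32, ENSRNOG00000034228.5 in 30 and ENSRNOG00000022932.4 in 27. These 32 settings leave out the replicate block, in which 0 genes were called.

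The letters A to F do not pair the dose groups: same-letter libraries correlated from -0.50 to 0.63 (mean 0.06), over 0.1 in 3 of 6 pairs, and 1 of 6 was best matched by its own letter. With the replicate block edgeR called 0 genes in D100 against D55 (5917 at an unadjusted p under 0.05); no other tool was run with the block. The gene list tests and their alternatives, and leaving out mitochondrially encoded genes, were not run, since identifiers had no names.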

Other observations

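The single most abundant gene took 17.2% ± 2.54 (SD, n = 4) of the counts in controls, 15.8% ± 4.01 (SD, n = 6) in D55 and 22.1% ± 1.78 (SD, n = 6) in D100; this difference was not tested on its own.

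Of the tested genes, 44 had a rounded count of 0 in at least 3 libraries and a count of at least 100 in at least 3 others, as ENSRNOG00000030351.4 did. In 33 of the 44, under 10% of the estimates that round to at least 1 and lie under 10000 were within 0.01 of a whole number, and the median over the 44 was 0%, against 100% over all tested genes. Of the 44, 1 was called in D100 against control, and 2 were at 0 in every library of a group.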
